A study of Homo sapiens with 20 samples.

How the data were processed

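Gene expression was measured by RNA sequencing in 20 libraries from HEK293T cells, an established human embryonic kidney line. Per the labels' protocols, SF3B1 and DDX42 were transfected transiently with a lipid reagent, RNA was extracted with RNAiso Plus, and libraries were made with the VAHTS Universal V6 kit. The transfection of DDX46 is given in the series' design text, which calls the 5 libraries of a group biological replicates without saying how they were separated. Each of 4 groups held 5 libraries: SF3B1 wild type (WT), SF3B1 with the K700E substitution (K700E), K700E together with DDX42, and K700E together with DDX46. The submitters' processing notes name Trim Galore 0.6.5, TopHat2 2.1.1, SAMtools 1.10 and the human build hg38 (GRCh38), without their roles. The authors deposited raw counts per feature and sample, as whole numbers with a different total in each file, and the counting tool, its annotation and its use of strand are not stated in the labels or file headers. Exon, intron and junction use were not analysed here.

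The sample files fell into 2 sets of 10 that list different features. Set 1 holds WT replicates 1 to 3, K700E replicates 1 to 3, and replicates 1 and 2 of both helicase groups. Set 2 holds the others. Both sets list the same 19974 Ensembl genes, all of which are in GENCODE release 29, which supplied symbols and GRCh38 positions, and 19922 of these are protein coding. Set 1 lists a further 7800 unannotated features named newGene and set 2 lists 7703. These numbers are given per set, so the 4398 names in both sets could not be joined, and the features were left out of the comparisons. They held 1.904% to 2.615% of the counts of a library. The deposited series-wide matrix, planned beforehand as the source of counts, was replaced by the sample files after its contents were seen. Its columns for set 2 were joined by position to lines that include 17 lines of text found only in the files of set 1, and so they are shifted against the gene identifiers from line 456 on. By identifier, 7.02% to 8.93% of the set 2 values equalled those in the sample files.

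Total counts ranged from 27779008 to 42348586 per library. Levels are given as CPM, counts scaled to library size, after scaling by trimmed means (TMM), with the standard deviation (SD) over 5 libraries. Counts from amplified libraries without molecular identifiers do not equal independent molecules. Genes were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr by group (14770 genes kept), robust quasi-likelihood fits of all 20 libraries, the file set as a covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05, two-sided. Log2 fold changes carry the standard error (SE) of the fit. There were 6 comparisons: K700E against WT, each helicase group against K700E and against WT, and the helicase groups against each other. Except for the source of counts, all of these choices, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

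Named genes were chosen as follows. SF3B1, DDX42 and DDX46 were named in every comparison. In K700E against WT and in each helicase group against K700E, the genes past the threshold with a mean of at least 1 CPM in at least 1 group gave the 8 with the highest log2 fold change, the 8 with the lowest and the 6 with the smallest p. Where fewer than 16 genes passed, the 16 with the smallest p were named. From each gene list past its threshold came the 3 members with the smallest p in its direction. PPOX, MAP3K7, TMEM14C and BRD9 were named in K700E against WT and in the DDX42 group against K700E, and the 5 genes with the smallest p in the other 3 comparisons. Of the 106 genes so named, 2 are not reported here, nor is the library that stood apart in 1 of them, though the counts include them. Of the 106, 38 overlap the span of another counted gene. Reads of such genes could be split between partners, so their values are uncertain, above all for gene models that span a pair of neighbouring genes.

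A set of 27 gene lists was written beforehand. They covered the U2 snRNP core without SF3B1, spliceosomal helicases without DDX42 and DDX46, branch point and 3 prime splice site recognition, SR proteins and hnRNPs, genes described elsewhere as mis-spliced with mutant SF3B1, nonsense-mediated decay factors, transcripts usually degraded by that pathway, p53 targets, endoplasmic reticulum stress and the integrated stress response, heat shock response, interferon response, NF-kB targets, immediate early genes, haem and iron-sulphur metabolism, mitochondrially encoded mRNAs, nuclear-encoded oxidative phosphorylation, cytosolic ribosomal proteins, cell cycle G2 and M, DNA replication and G1/S, replication-dependent histones, cholesterol biosynthesis, hypoxia and glycolysis, nuclear and small structural RNAs, and markers of blood cells, fibroblasts, squamous and simple epithelium, and hepatocytes. Lists were tested with camera on voom values (limma 3.58.1) with a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, each adjusted over the 26 lists with at least 3 tested members. The list of nuclear and small structural RNAs had 0 tested members.

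Reversal of the K700E change was measured as the covariance across genes of the log2 fold changes of K700E against WT and of a helicase group against K700E. Shared K700E libraries make this covariance negative without any effect. It was therefore set beside 20 simulated sets of unchanged groups, and repeated over 10 splits of the K700E libraries that leave none in both comparisons. The overlap of the helicase changes was treated in the same way. The fits were tested on simulated data with 200 genes changed by known folds, 50 per fold. Median fitted changes lay close to the true ones, but recovery depended on size. In K700E against WT (14644 genes) the test called 22% of genes changed 1.25-fold, 70% at 1.5-fold, 90% at 2-fold and 100% at 4-fold. The shares were 16%, 66%, 88% and 96% for the DDX42 group against K700E (14634 genes), and 12%, 60%, 88% and 98% for the DDX46 group against K700E (14643 genes). Of the calls, 1.53% to 2.92% were genes left unchanged. A list raised 1.25-fold in a simulated DDX42 group was the 1 list past the threshold. The simulated genes were drawn independently of each other. These data therefore could not show false calls that arise from correlated genes or from sets of libraries that deviate together.

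Pairing by replicate number was checked from correlations between groups of each library's deviation from its group mean. All 5 numbers of the DDX42 and DDX46 groups deviated together (r from 0.17 to 0.39, above 0.1 in 5 of 5), and values with a replicate block are given for that comparison. Over the 30 number pairs of all groups, 16 exceeded 0.1 and the lowest was -0.29, and the other comparisons were not paired by number. Equal numbers of WT and K700E were also linked, with r from 0.0654 to 0.430, above 0.1 in 4 of 5. This check covered equal numbers only. K700E replicate 3 had r = -0.29 with DDX42 group replicate 3, and up to 0.39 with DDX42 group libraries of other numbers. Links between libraries of different numbers were not part of the main fit. Alternatives were no file-set covariate, a replicate block with and without it, each file set alone, DESeq2 1.42.0, other scaling factors, scaling without the transfected genes, other low-count filters, voom with sample weights, a minimum fold of 1.2, the compared groups alone, and leaving out each library in turn. Chosen after seeing the data were 3 surrogate variables (sva 3.50.0) and a replicate block in a fit of the 2 helicase groups. So was a correction of each library for GC content and length by splines with 4 degrees of freedom. The series-wide matrix as deposited, first planned as the main source of counts, became an alternative after the data were seen. Other splits of the samples were drawn with 40 per comparison, the real split included. Added after seeing the data, for the 5 comparisons with a helicase group, were all splits that keep 3 sets of libraries, found by clustering the residuals after group and file set, as in the real groups (54 against K700E, 36 in the others). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.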

Results

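RNA of 20 libraries of HEK293T cells was sequenced, with 5 libraries in each of 4 groups: WT SF3B1, SF3B1-K700E (K700E), K700E with DDX42, and K700E with DDX46. SF3B1 is a core protein of the U2 snRNP, which recognises the branch point in splicing, and DDX42 and DDX46 are RNA helicases known to bind it. Total counts ranged from 27779008 to 42348586 per library, and 14770 genes were tested. The series title concerns an effect of DDX42 on splicing altered by K700E. The deposited values are counts per gene, so the comparisons below address transcript levels and not splicing, and they cannot show which SF3B1 sequence was expressed.

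Each transfected helicase was far higher in its own group than elsewhere. DDX42 (ENSG00000198231, GRCh38 chromosome 17, 63773603 to 63819317) reached 43743 ± 13636 CPM (SD, n = 5) in the DDX42 group, against 280 ± 135 CPM in K700E, 222 ± 12.1 CPM in WT and 233 ± 27.6 CPM in the DDX46 group. The log2 fold change against K700E was 7.24 (SE 0.24, adjusted p = 1.04e-12, edgeR). DDX46 (ENSG00000145833, chromosome 5, 134758771 to 134855133) reached 15072 ± 3928 CPM in the DDX46 group, against 216 ± 17.8 CPM in K700E, 241 ± 42.9 CPM in WT and 281 ± 27.6 CPM in the DDX42 group. Its log2 fold change against K700E was 6.10 (SE 0.18, adjusted p = 4.34e-15). SF3B1 (ENSG00000115524, chromosome 2, 197389784 to 197435091) was at 1361 ± 231 CPM in WT, 1074 ± 117 CPM in K700E, 1353 ± 300 CPM in the DDX42 group and 2641 ± 468 CPM in the DDX46 group. SF3B1 was higher in the DDX46 group than in K700E (log2 fold change 1.27, SE 0.15, adjusted p = 1.37e-04), WT (0.92, SE 0.14, adjusted p = 0.00382) and the DDX42 group. The DDX42 group lay below it by a log2 fold change of -0.97 (SE 0.14, adjusted p = 0.00282). The SF3B1 differences of K700E from WT (-0.34, SE 0.14, adjusted p = 0.999) and of the DDX42 group from K700E (0.30, SE 0.14, adjusted p = 0.260) did not pass. Within file set 1 alone the SF3B1 difference of the DDX46 group from K700E was 1.21 (adjusted p = 0.0751) and within set 2 alone 1.32 (adjusted p = 0.0924), where the adjusted p over all alternatives ran from 2.02e-16 to 0.0924. Counts per gene do not separate transcripts of a construct from those of the cell's own gene.

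**Figure D1:**
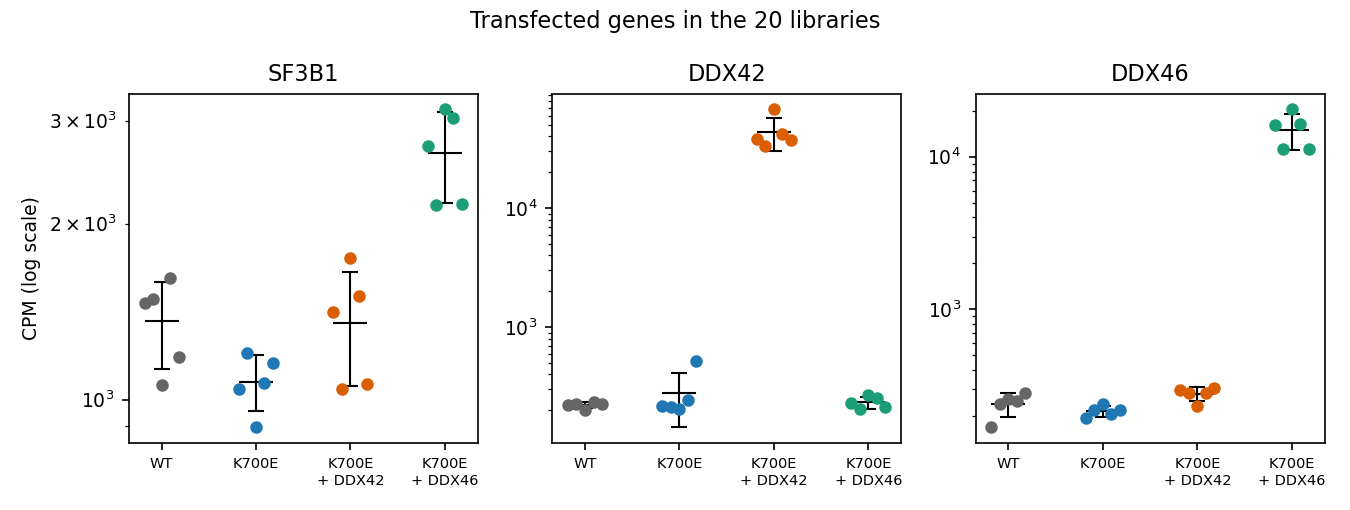
CPM of SF3B1, DDX42 and DDX46 on log axes in the 20 libraries, as points by group, with the mean as a horizontal line and the SD over 5 libraries as bars. DDX42 averaged 43743 CPM in its own group and DDX46 15072 CPM in its own, and SF3B1 was highest in the DDX46 group at 2641 CPM.

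K700E was set against WT to ask which transcripts differ with the mutant. No gene passed the threshold. The gene model AC004922.1, which spans ARPC1A and ARPC1B and whose reads are therefore uncertain, had 0.950 ± 0.860 CPM in K700E and 4.84 ± 1.33 CPM in WT (log2 fold change -2.44, SE 0.51), with all 5 K700E libraries below every WT library. PHGDH, the first enzyme of serine synthesis from glycolysis (ENSG00000092621, chromosome 1, 119648411 to 119744226), had 464 ± 19.9 CPM in K700E and 531 ± 19.4 CPM in WT (-0.20, SE 0.05). GBE1, the glycogen branching enzyme, had a log2 fold change of -0.31 (SE 0.09). Both again held in 5 of 5 libraries. Further genes with the smallest p were ABHD14A-ACY1 (1.94, a model spanning neighbouring genes), WDR55 (0.23), NSMCE4A (-0.24), MED23 (-0.24), DPP7 (0.63), UAP1L1 (0.35) and RELL2 (0.37). Others were XRCC3 (0.34), NOSTRIN (0.86), LMO1 (1.01), ETV5 (-0.83), and the overlapping models AL357673.1 (1.47) and CDRT4 (-3.33), none of which passed. Of the genes described elsewhere as mis-spliced with mutant SF3B1, PPOX differed by 0.18, MAP3K7 by -0.18, and BRD9 and TMEM14C by 0.00. PHGDH and MAP3K7, 2 of the 20 measured members of that list, passed when adjusted over the list alone (adjusted p = 0.0191 and 0.0460) and 0 passed over all genes. The list as a whole did not pass (camera adjusted p = 0.526), and its median and mean lay just above 0 where the direction of the test was lower.

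In each comparison other splits of the libraries gave as many lists by camera, as given below, so chance could not be excluded for the list counts. The list of cell cycle G2 and M genes was lower in K700E by camera (adjusted p = 2.58e-05, median log2 fold change -0.09), with 3 of 30 members above 0, as was hypoxia and glycolysis (adjusted p = 0.00136) with 4 of 29 above 0. With an estimated correlation these gave adjusted p = 0.880 and adjusted p = 0.892, and 0 members of either passed, over all genes or adjusted over the list alone. Examples are CENPE (-0.36), ASPM (-0.26) and DLGAP5 (-0.20), and ADM (-0.22), P4HA1 (-0.14) and ANKRD37 (-0.49). By edgeR 0 genes passed, the smallest adjusted p was 0.999, and 264 genes had an unadjusted p under 0.05, where 738.5 would by chance. The main fit left out the 3 sets of libraries that deviate together, described below. It also left out the link between equal numbers of WT and K700E (r above 0.1 in 4 of 5). The count of 0 therefore does not show that no transcript differs. With a replicate block, with or without the file set, the count was also 0. DESeq2 called 2 genes (AC004922.1 and ABHD14A-ACY1) and voom with sample weights called 1 (AC004922.1). With 3 surrogate variables 4 genes passed, PHGDH, XRCC3, DPP7 and DCAF16 (0.27, named after its value was seen), with adjusted p from 0.0284 to 0.0414. Over all alternatives the adjusted p of PHGDH, XRCC3 and DPP7 ran up to 1.00. The call for hypoxia and glycolysis ended without WT replicate 1 (adjusted p = 0.0890) and within file set 2 (adjusted p = 0.226, where it ran from 8.88e-09 over the alternatives). That for G2 and M ended within file set 1 (adjusted p = 0.343, from 5.20e-08). The count of lists, 2 over all libraries, was 7 without WT replicate 3 or 5, 5 without K700E replicate 1, 4 without K700E replicate 2 or 4, and 6 without K700E replicate 5.

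The DDX42 group was set against K700E to ask what changes when DDX42 is added to the mutant. The genes that rose most were FCAMR, an Fc receptor (log2 fold change 3.41, SE 0.51), NPR3, the natriuretic peptide clearance receptor (2.18, SE 0.25), C1orf116 (2.09, SE 0.20) and CCDC168 (1.75). Next came the overlapping model AC010197.2 (1.69), MYLK2, a myosin light chain kinase (1.29), the chemokine receptor CCR6 (1.24) and CMYA5 (1.24). C1orf116 (ENSG00000182795, chromosome 1, 207018521 to 207032756) went from 2.17 ± 0.584 to 9.50 ± 1.80 CPM (adjusted p = 2.74e-06) in 5 of 5 libraries. NPR3 (ENSG00000113389, chromosome 5, 32689070 to 32791724) went from 2.09 ± 0.627 to 9.66 ± 1.52 CPM (adjusted p = 5.18e-05) in 5 of 5. The genes that fell most were CDK5R2, an activator of CDK5 (-1.52), RTEL1-TNFRSF6B (-1.47, a model spanning neighbouring genes), TTC34 (-1.42), ARHGAP4 (-1.30), the plexin PLXNB3 (-1.18), CCDC157 (-1.17), DPP7 (-1.17) and INSC (-1.04). Among the smallest p values were those of FDXR, mitochondrial ferredoxin reductase and a p53 target (34.7 ± 1.68 against 65.5 ± 8.44 CPM, -0.90, adjusted p = 5.35e-05), PPP2R5B, a PP2A subunit (-0.64, adjusted p = 5.18e-05), and TUBGCP6 of the gamma-tubulin complex (-0.59, adjusted p = 5.34e-04).

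By list, cell cycle G2 and M genes were higher in the DDX42 group (camera adjusted p = 1.73e-09, and adjusted p = 0.242 with an estimated correlation), with 28 of 30 members above 0. Of these members 6 rose and 12 did when adjusted over the list alone, such as CCNB1 (0.38), BIRC5 (0.25) and KIF23 (0.31), and fry gave adjusted p = 0.00850. Cytosolic ribosomal proteins were higher in 74 of 75 members with a median of 0.14 (adjusted p = 4.43e-12, and adjusted p = 0.780 with an estimated correlation). RPL6 (0.24) and RPS27A (0.22) rose, 4 members rose when adjusted over the list alone, and RPL7 (0.27) had adjusted p = 0.0527. SR proteins and hnRNPs (21 of 22 members above 0, adjusted p = 7.49e-04), heat shock genes (16 of 18, adjusted p = 0.00276) and nuclear-encoded oxidative phosphorylation (38 of 46, adjusted p = 0.00200) were also higher by camera, with 0 members passing in each, over all genes or adjusted over the list alone. With an estimated correlation these gave adjusted p = 0.780, adjusted p = 0.780 and adjusted p = 0.824. Their members with the smallest p were SRSF11 (0.18), SRSF3 (0.13) and SRSF9 (0.25), HSPA4 (0.16), DNAJA1 (0.28) and HSPD1 (0.25), and COX6C (0.33), COX7C (0.26) and UQCRB (0.22). Of the genes described as mis-spliced, BRD9 differed by -0.18, PPOX by -0.22, TMEM14C by 0.11 and MAP3K7 by 0.08, none passing. The call for SR proteins and hnRNPs ended after the GC and length correction (adjusted p = 0.102, from 7.16e-09 over the alternatives). That for oxidative phosphorylation ended without DDX42 group replicate 5 (adjusted p = 0.196, from 7.49e-10), without the file-set covariate (adjusted p = 0.218), with a replicate block (adjusted p = 0.195) and within file set 2 (adjusted p = 0.209).

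In this comparison 382 genes passed, 127 higher and 255 lower, and 24 of them changed more than 2-fold, 14 higher and 10 lower. Their median absolute log2 fold change was 0.39, and 18 genes passed against a minimum fold of 1.2. The count was 56 without K700E replicate 4, 74 without K700E replicate 1, 251 without K700E replicate 2, 205 without K700E replicate 5, 86 without DDX42 group replicate 1 and 87 without its replicate 2, and within each file set alone 3 genes passed. After the GC and length correction 143 passed, of which 104 were among the 382. Of 24 named calls, 13 held without any 1 library (FCAMR, NPR3, C1orf116, CCDC168, MYLK2, CCR6, CMYA5, PLXNB3, CCDC157, DPP7, PPP2R5B, FDXR and TUBGCP6). Of the others 11 ended without K700E replicate 4 (adjusted p 0.0516 to 0.203), 9 without K700E replicate 1 (0.0564 to 0.127), 4 without K700E replicate 2 (0.0537 to 0.0765), and 4 without K700E replicate 5 (0.0562 to 0.0815). Of the DDX42 group, 9 ended without replicate 1 (0.0587 to 0.128), 7 without replicate 2 (0.0532 to 0.120), 1 without replicate 3 (0.0595), 2 without replicate 4 (0.0517 to 0.0715) and 4 without replicate 5 (0.0567 to 0.108). RPL7 passed without K700E replicate 3 (adjusted p = 0.0382) and without DDX42 group replicate 3 (adjusted p = 0.0263).

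**Figure D2:**
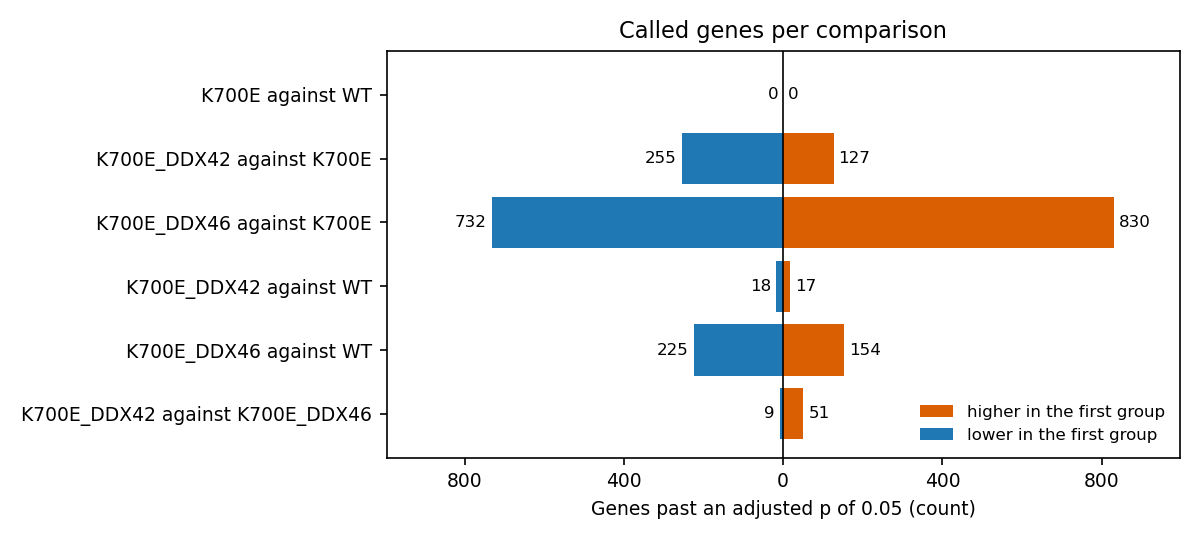
Number of genes past an adjusted p of 0.05 in each of the 6 comparisons, drawn to the right where higher and to the left where lower in the group named first. The DDX46 group against K700E has the most, 830 higher and 732 lower, and K700E against WT has 0.

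The DDX46 group was set against K700E to ask the same of DDX46. SF3B1 was also higher in the DDX46 group (2641 against 1074 CPM), so this comparison does not separate DDX46 from the amount of SF3B1. The genes that rose most were FCAMR (2.09), ANKRD1, an ankyrin repeat protein of muscle (1.46, SE 0.25), ZC3H12D (1.44), the G protein regulator RGS4 (1.23), the transcription factor ETV5 (1.18), and the overlapping models CDRT4 (3.15, SE 0.95), PMF1-BGLAP (2.05) and AC093155.3 (1.28). Those that fell most were GLT1D1 (-2.25, SE 0.40), TTC34 (-1.83), the R-spondin receptor LGR6 (-1.75), C16orf71 (-1.60), AMER2 (-1.59), XKR7 (-1.53) and COPZ2 (-1.53). INKA2 (ENSG00000197852, chromosome 1, 111680630 to 111739424) fell from 27.0 ± 2.47 to 14.3 ± 1.98 CPM (-0.95, SE 0.10, adjusted p = 4.72e-05). LMOD1 (-0.87), the hedgehog acyltransferase HHAT (-0.83), FDXR (-0.81) and the DNA helicase DDX11 (-0.46) fell with the next smallest p, each in 5 of 5 libraries. WDR82 rose from 193 ± 8.74 to 257 ± 16.7 CPM (0.39, adjusted p = 3.31e-04).

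Lists of the splicing machinery were higher in the DDX46 group than in K700E by camera. In 19 of 40 splits of these libraries, the real one included, as many lists passed. The U2 snRNP core without SF3B1 was higher in 11 of 11 members (camera adjusted p = 1.44e-04, and adjusted p = 0.216 with an estimated correlation). Of these 4 rose, and 8 when adjusted over the list alone, such as SF3B6 (0.19), SF3B3 (0.25) and SF3B2 (0.24). Other spliceosomal helicases were higher in 14 of 14 (adjusted p = 6.77e-05, and adjusted p = 0.316 with an estimated correlation). Of these 4 rose, and 6 over the list alone, such as DHX15 (0.34), DDX5 (0.29) and EIF4A3 (0.28). SR proteins and hnRNPs were higher in 22 of 22 (adjusted p = 5.30e-08, and adjusted p = 0.231 with an estimated correlation), of which 5 rose, and 14 over the list alone, such as HNRNPC (0.25), HNRNPK (0.22) and SRSF3 (0.20). SF3B1 itself, which is in none of these lists, was 1.27 higher.

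Chaperone, ribosomal and cell cycle lists were higher as well. Heat shock genes had a median of 0.26 (adjusted p = 7.14e-07, and adjusted p = 0.231 with an estimated correlation), with 7 of 18 rising, 13 over the list alone, such as HSPA8 (0.58), DNAJA1 (0.47) and STIP1 (0.30). Endoplasmic reticulum stress genes (adjusted p = 0.00604, and adjusted p = 0.216 with an estimated correlation) had 6 of 24 rising, by either adjustment, such as HSPA5, the main chaperone of that compartment (0.35), PDIA4 (0.23) and PSAT1 (0.22). All 75 ribosomal protein genes lay above 0 with a median of 0.19 (adjusted p = 1.04e-17, and adjusted p = 0.392 with an estimated correlation), and 13 rose, 41 over the list alone, such as RPL5 (0.25), RPL6 (0.26) and RPS7 (0.22). Oxidative phosphorylation was higher in 45 of 46 (adjusted p = 5.30e-08, and adjusted p = 0.478 with an estimated correlation), with 8 rising, 13 over the list alone, such as ATP5F1A (0.20), ATP5PB (0.19) and SDHB (0.21). Of the G2 and M genes 10 of 30 rose, 12 over the list alone, such as CCNB1 (0.38), BIRC5 (0.25) and UBE2C (0.41) (adjusted p = 5.06e-07, and adjusted p = 0.216 with an estimated correlation). The p53 targets were lower (adjusted p = 0.00562, and adjusted p = 0.638 with an estimated correlation), with 5 of 23 above 0, and 3 fell by either adjustment: FDXR (-0.81), DDB2 (-0.83), a DNA damage recognition protein, and the translesion polymerase POLH (-0.43).

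In this comparison 1562 genes passed, 830 higher and 732 lower, against 457 higher and 1043 lower with upper quartile scaling. More than 2-fold changes were found for 97 genes, 15 higher and 82 lower, the median absolute log2 fold change was 0.33, and 42 genes passed against a minimum fold of 1.2. The count was 454 without K700E replicate 4, 707 without K700E replicate 1, 789 without DDX46 group replicate 1 and 959 without its replicate 4, and within each file set alone 1 gene passed. Of 48 named calls, 22 held without any 1 library (among them ANKRD1, ETV5, GLT1D1, TTC34, INKA2, FDXR, HHAT, WDR82, DHX15, DDX5, DDB2, HSPA8, RPL5 and CCNB1). Of the others 26 ended without K700E replicate 4 (adjusted p 0.0541 to 0.137), 13 without K700E replicate 1 (0.0504 to 0.110), 5 without K700E replicate 2 (0.0555 to 0.1003), 4 without K700E replicate 3 (0.0545 to 0.0800), and 5 without K700E replicate 5 (0.0514 to 0.0817). Of the DDX46 group, 12 ended without replicate 1 (0.0521 to 0.152), 3 without replicate 2 (0.0559 to 0.112), 3 without replicate 3 (0.0550 to 0.0561), 9 without replicate 4 (0.0520 to 0.0981) and 5 without replicate 5 (0.0504 to 0.0766). Upper quartile scaling ended the calls of SF3B6, SF3B2, PDIA4, PSAT1, ATP5F1A, ATP5PB and SDHB, and of RPS27A in the DDX42 group, without turning their direction.

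**Figure D3:**
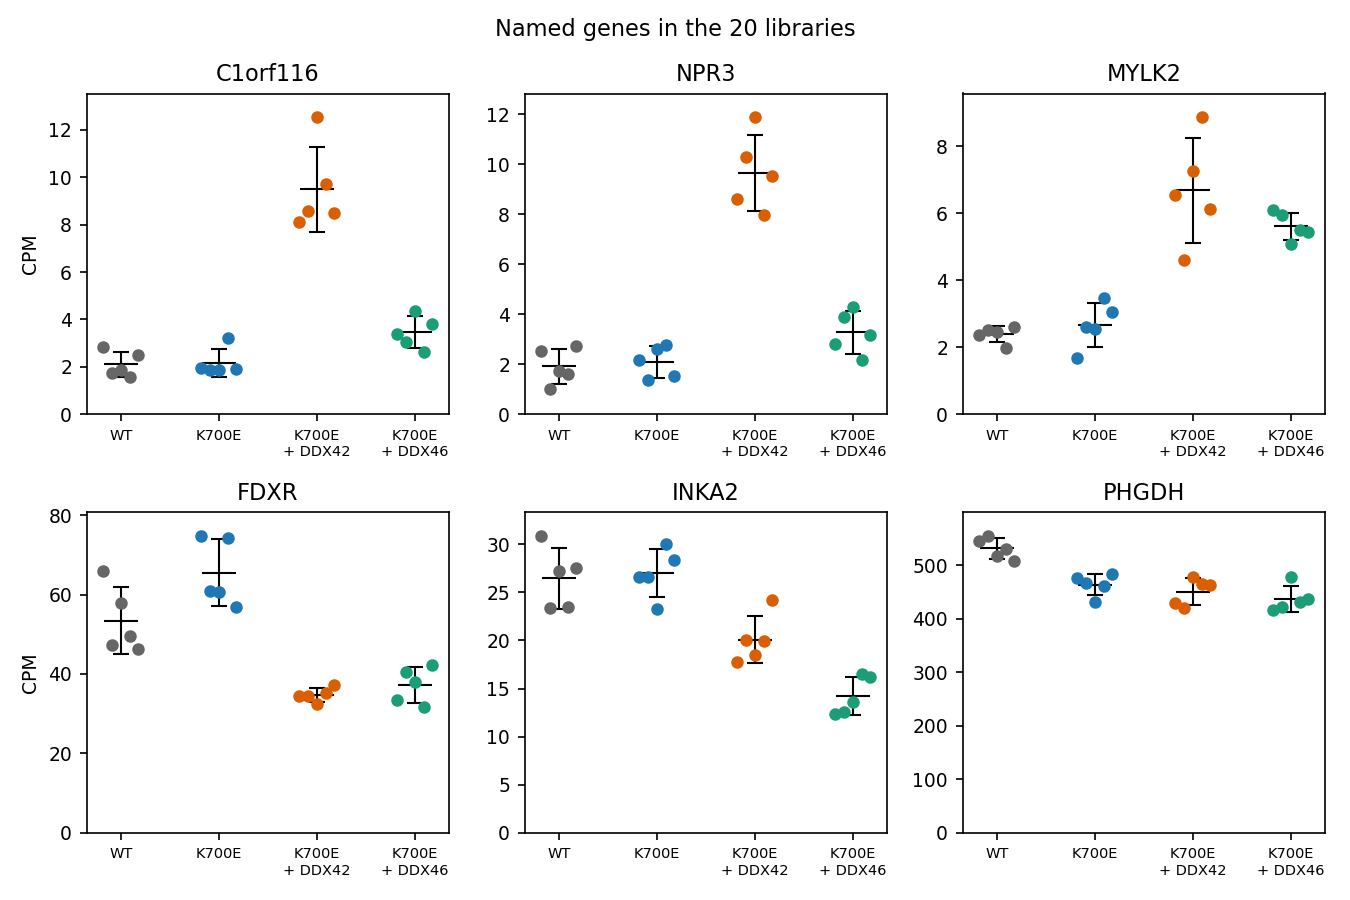
CPM of 6 named genes in the 20 libraries, as points by group, with the mean as a horizontal line and the SD over 5 libraries as bars. C1orf116 and NPR3 stand highest in the DDX42 group, at 9.50 and 9.66 CPM, FDXR is lower in both helicase groups than in K700E, and PHGDH is highest in WT at 531 CPM.

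**Figure D4:**
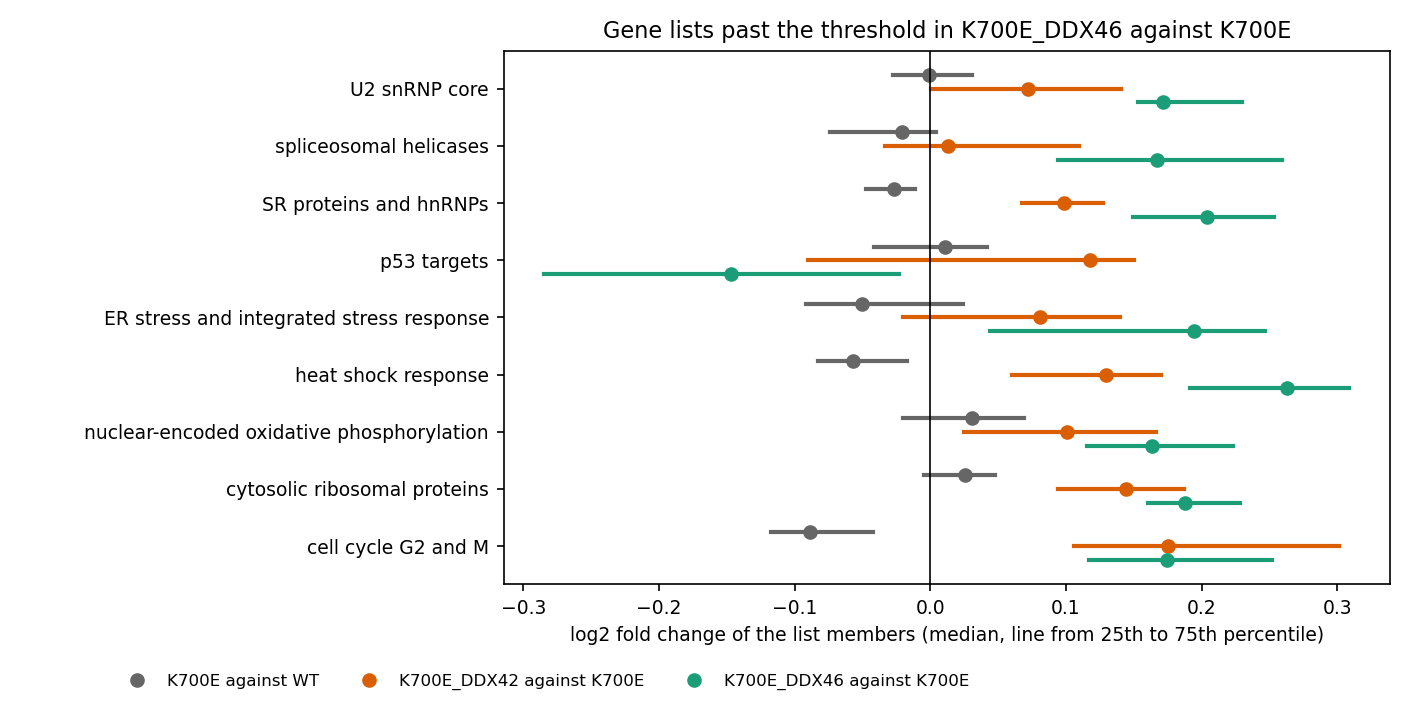
Log2 fold changes of the members of the 9 lists past the threshold in the DDX46 group against K700E, as medians with lines from the 25th to the 75th percentile, in 3 comparisons. In that comparison 8 lists lie above 0, such as heat shock at 0.26, and p53 targets lie below 0.

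Whether adding a helicase turns back the K700E change was measured across 13252 genes. Log2 fold changes of the DDX42 group against K700E and of K700E against WT correlated with r = -0.504 across genes (rho -0.601), with a covariance of -0.0256. Simulated unchanged groups sharing K700E libraries gave r = -0.477 (-0.608 to -0.312) and a covariance of -0.0213. For DDX46 r was -0.458 (rho -0.472) and the covariance -0.0250, against -0.486 (-0.628 to -0.350) and -0.0216. With the K700E libraries split so that none was shared, the covariance averaged -0.00902 (SD 0.00579 over 10 splits) for DDX42 and -0.00833 (SD 0.00595) for DDX46, below 0 in 9 of 10 splits each. Genes are not independent replicates, and these splits reuse the same libraries. K700E holds 2, 2 and 1 libraries of 3 sets that deviate together, described below, and each other group 1, 2 and 2. Such an imbalance can make the covariance negative without any reversal, also where no library is shared. The simulation leaves the sets out, and the splits do not balance them. Less the part that the shared libraries give, taken from the fitted variances and scaled by the simulation, the covariance was -0.00368 for DDX42 and -0.00285 for DDX46, and it turned to 0.00714 and 0.00879 without K700E replicate 1. It lay between -0.00952 and -0.0157 for either helicase without WT replicate 1, without K700E replicate 2, 3 or 5, and, for DDX42, without DDX42 group replicate 3.

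Calls against K700E overlapped between the helicase groups. Of the 381 genes called in the DDX42 group and 1560 called in the DDX46 group against K700E, leaving out the transfected genes, 255 changed in the same direction, 86 higher and 169 lower, and 1 in the opposite one. FDXR, TTC34 and DDB2 fell and CCNB1, BIRC5 and RPL6 rose in both. Independent lists of these sizes would share 7.06 higher and 12.6 lower, though these comparisons share the K700E libraries. The log2 fold changes correlated with r = 0.662 across genes with a covariance of 0.0477, against 0.503 and 0.0225 in simulated unchanged groups sharing K700E libraries. With the K700E libraries split, the covariance averaged 0.0306, and 9.1 genes (1 to 52) were shared on average. Libraries of the same number in the 2 helicase groups deviate together (r from 0.167 to 0.388 in 5 of 5), which raises this covariance without any effect. The simulation leaves that link out and the split libraries keep it, so neither separates it from a shared change. Neither accounts for the 3 sets of libraries described below. K700E replicates 1 and 4 lie in a set of which K700E holds 2 libraries and each other group 1. The count of 255 was 27 without K700E replicate 4, 48 without K700E replicate 1, 151 without K700E replicate 5, 62 without DDX42 group replicate 1, 60 without its replicate 2 and 168 without its replicate 5.

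Against WT, the DDX42 group showed higher CCR6 (log2 fold change 1.81, SE 0.19), NPR3 (2.31), C1orf116 (2.11), MYLK2 (1.44) and CMYA5 (1.41), with adjusted p from 2.63e-06 to 1.49e-04, each in 5 of 5 libraries. Ribosomal protein genes were higher in 75 of 75 (camera adjusted p = 5.95e-24), oxidative phosphorylation in 40 of 46 (adjusted p = 6.06e-07) and G2 and M genes in 25 of 30 (adjusted p = 2.15e-05, 3 rising over the list alone). With an estimated correlation these 3 lists had adjusted p from 0.529 to 0.577, as had all 8 lists called here. Also higher were SR proteins and hnRNPs in 21 of 22 (adjusted p = 0.00338), mitochondrially encoded mRNAs in 13 of 13 (adjusted p = 0.00343) and heat shock genes in 15 of 18 (adjusted p = 0.0135), each with adjusted p = 0.577 with an estimated correlation. So were the 4 measured hepatocyte markers CYP3A4, HP, TF and ALB in 4 of 4 (adjusted p = 0.0178, and adjusted p = 0.529 with an estimated correlation). Histone genes were lower (4 of 21 above 0, adjusted p = 0.00250, and adjusted p = 0.577 with an estimated correlation), of which HIST1H1C fell (-0.62, adjusted p = 0.0425). After the GC and length correction the mitochondrially encoded mRNAs turned lower (adjusted p = 0.0801), and their call also ended within file set 2 and without WT replicate 5 (adjusted p = 0.103 and 0.0509, from 1.52e-04 over the alternatives). The call for SR proteins and hnRNPs ended after that correction and without WT replicate 5 (adjusted p = 0.0613 and 0.0509, from 1.59e-07). That for heat shock ended within file set 2 and without WT replicate 1 (adjusted p = 0.531 and 0.129, from 4.51e-04). Those for G2 and M (adjusted p = 0.576, from 2.17e-06) and histones (adjusted p = 0.0974, from 3.49e-06) ended within file set 2. That for hepatocyte markers ended in 6 alternatives (adjusted p from 0.00140 to 0.666 over all), among them without WT replicate 3 (0.0768), WT replicate 5 (0.143) or DDX42 group replicate 3 (0.0800), within file set 1, without a low-count filter and with a replicate block and the file set. In all 35 genes passed, 17 higher and 18 lower, 12 of them over 2-fold, and 31 of the 34 besides DDX42 were among those called against K700E. The count was 19, 23, 20 and 17 without WT replicates 1, 2, 3 and 4, and 13, 15, 18 and 21 without DDX42 group replicates 1, 2, 3 and 4, and the count of lists was 5 without WT replicate 5.

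The DDX46 group against WT showed lower INKA2 (-0.93, SE 0.10), HHAT (-0.82), KANK3 (-1.03) and DZIP3 (-0.64) and higher MYLK2 (1.2), with adjusted p from 7.55e-05 to 0.00214. Ribosomal protein genes were higher in 75 of 75 (camera adjusted p = 6.57e-27), 5 rising and 66 over the list alone, and oxidative phosphorylation in 45 of 46 (adjusted p = 2.66e-12, 1 rising and 4 over the list alone). With an estimated correlation both had adjusted p = 0.314, and the 11 lists called here ran from 0.314 to 0.658. The U2 snRNP core was higher in 11 of 11 (adjusted p = 4.52e-05), helicases in 14 of 14 (adjusted p = 1.71e-04), SR proteins and hnRNPs in 22 of 22 (adjusted p = 1.97e-07) and heat shock genes in 17 of 18 (adjusted p = 2.95e-06), with adjusted p from 0.314 to 0.319 with an estimated correlation. Also higher were G2 and M genes in 23 of 30 (adjusted p = 9.05e-04), endoplasmic reticulum stress in 18 of 24 (adjusted p = 0.0361), haem and iron-sulphur genes in 21 of 26 (adjusted p = 0.0361) and mitochondrially encoded mRNAs in 12 of 13 (adjusted p = 0.0347). With an estimated correlation these 4 had adjusted p = 0.366, adjusted p = 0.314, adjusted p = 0.462 and adjusted p = 0.658. The p53 targets were lower (4 of 23 above 0, adjusted p = 6.06e-04, and adjusted p = 0.547 with an estimated correlation). After the GC and length correction the mitochondrially encoded mRNAs turned lower (adjusted p = 0.137). Their call also ended with 3 surrogate variables (0.138), in 3 other settings, and without WT replicate 1 (0.0945), WT replicate 5 (0.0801) or DDX46 group replicate 2 (0.0890) or 3 (0.193), from 0.00476 over the alternatives. That for endoplasmic reticulum stress ended after the GC and length correction (adjusted p = 0.124), in 4 other settings, and without WT replicate 3 (0.0739), WT replicate 5 (0.147) or DDX46 group replicate 3 (0.112), from 0.00310 to 0.149 over the alternatives. That for haem and iron-sulphur genes ended after that correction (adjusted p = 0.258), in 4 other settings, and without WT replicate 4 (0.0671), WT replicate 5 (0.0677) or DDX46 group replicate 5 (0.140), from 0.00305. Within file set 2 the calls for p53 targets (adjusted p = 0.297, from 2.06e-07) and G2 and M (adjusted p = 0.569, from 4.69e-05) ended, the last also without WT replicate 1 (0.0503). In all 379 genes passed, 154 higher and 225 lower (93 and 294 with upper quartile scaling), 37 of them over 2-fold, and 337 of the 377 besides SF3B1 and DDX46 were among those called against K700E. The count was 242, 194, 145, 138 and 247 without WT replicates 1 to 5 and 76, 221, 899, 107 and 217 without DDX46 group replicates 1 to 5.

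Between the helicase groups, the DDX42 group had higher AVPR1A, a vasopressin receptor (1.48, SE 0.17, adjusted p = 7.31e-05), PTCHD4 (1.40), SLC44A5 (0.73), C1orf116 (1.45) and NPR3 (1.56, adjusted p = 0.00325), each in 5 of 5 libraries. The p53 targets were higher in 21 of 23 (camera adjusted p = 7.05e-06), 1 rising (SPATA18, 0.49) and 9 over the list alone, and hepatocyte markers in 4 of 4 (adjusted p = 0.00582), 2 over the list alone (ALB, 1.27, and TF). With an estimated correlation both had adjusted p = 0.414, and the 10 lists called here ran from 0.414 to 0.731. Lower were the U2 snRNP core (2 of 11 above 0, adjusted p = 0.00422), helicases (1 of 14, adjusted p = 1.13e-04), branch point recognition (3 of 15, adjusted p = 0.0327) and SR proteins and hnRNPs (3 of 22, adjusted p = 7.15e-04), each with adjusted p = 0.414 with an estimated correlation. So were heat shock (3 of 18, adjusted p = 8.12e-04), oxidative phosphorylation (6 of 46, adjusted p = 3.77e-04), ribosomal proteins (6 of 75, adjusted p = 3.77e-04) and DNA replication (5 of 34, adjusted p = 8.12e-04). In that order these 4 had adjusted p = 0.414, adjusted p = 0.615, adjusted p = 0.731 and adjusted p = 0.414 with an estimated correlation. The call for branch point recognition ended after the GC and length correction (adjusted p = 0.0696), in 3 other settings, and without DDX42 group replicate 2 (0.119) or 5 (0.117) or DDX46 group replicate 1 (0.142), 3 (0.123) or 4 (0.128), from 0.00324 to 0.150 over the alternatives. That for oxidative phosphorylation ended with 3 surrogate variables (adjusted p = 0.0570) and without DDX42 group replicate 3 (0.169, from 3.67e-08). That for ribosomal proteins ended without that library (adjusted p = 0.513, from 2.77e-14). That for hepatocyte markers ended within file set 1 (adjusted p = 0.323, from 7.63e-04) and without a low-count filter (0.254). In all 60 genes passed, 51 higher and 9 lower, 13 of them over 2-fold. With the replicate number as a block, which the numbers of these groups support, 306 passed in a fit of the 2 groups and 215 in the fit of all libraries with the file set, and 53 without the file set. The count was 16, 37, 21 and 21 without DDX42 group replicates 1 to 4 and 20, 33, 94, 21 and 31 without DDX46 group replicates 1 to 5.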

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

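The search of named genes for a library far from the other 4 of its group was fixed before the result was seen. The tests of the unannotated features were chosen after seeing the files. No explanation was tested for any of these values.

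Of 248 groups of 5 values of named genes, 12 held a library set apart from the others, where 12.4 would be by chance at 1 in 20. DDX42 stood at 519 CPM in K700E replicate 5, against 205 to 246 CPM in the other K700E libraries, and at 67561 CPM in DDX42 group replicate 3, against 33502 to 41778 CPM in the others of that group. That same library held BRD9 at 56.1 CPM, against 48.1 to 50.01 CPM, and the chaperonin gene HSPD1 at 1195 CPM, against 1338 to 1380 CPM. CDRT4, whose model overlaps TVP23C, stood apart in 3 groups, at 15.03 CPM in WT replicate 2 (others 2.32 to 5.47), 2.12 CPM in K700E replicate 1 (others 0.0617 to 0.504) and 11.9 CPM in DDX46 group replicate 2 (others 0.286 to 3.32). C1orf116 was at 3.21 CPM in K700E replicate 4 (others 1.87 to 1.95). PMF1-BGLAP was at 11.5 CPM in K700E replicate 2 (others 2.04 to 3.84) and KIF23 at 106 CPM in K700E replicate 3 (others 98.0 to 99.3). HHAT was at 7.69 CPM in DDX46 group replicate 1 (others 11.1 to 11.7).

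Among the unannotated features, which the comparisons of the report leave out, 2 had 0 counts in every WT library of their file set and more than 3 counts in every library with K700E. In set 1, newGene_4062 had 0 counts in 3 WT libraries and 42 to 79 counts in the 7 others, with a lowest level of 1.36 CPM. It passed in K700E against WT (adjusted p = 0.00753, edgeR, within set 1) and in the 3 K700E groups together against WT (adjusted p = 0.00149). In set 2, newGene_10519 had 0 counts in 2 WT libraries and 23 to 190 counts in the 8 others, with a lowest level of 0.645 CPM, and did not pass (adjusted p = 0.541 for the 3 groups together). The files used here give no position for these features, and the names are counted per set, so the features cannot be matched between sets.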

How the results depend on the processing

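Surrogate variables, the GC and length correction and the replicate block in a fit of 2 groups were chosen only after the results were seen. The series-wide matrix as deposited, planned as the main source of counts, became an alternative after its shift was seen. Of 1078 values for 45 list calls, 1013 kept their direction and call, 63 no longer passed, and 2 turned: after the GC and length correction the mitochondrially encoded mRNAs were lower, no longer passing, than WT in the DDX42 group (adjusted p signed by direction -0.0801) and the DDX46 group (-0.137). The covariance less the shared part, which has no call, turned above 0 without K700E replicate 1. Of 3352 values for 129 results of named genes under all settings, 2904 kept their direction and side of the threshold, 417 kept the direction and no longer passed, and 31 came to pass. Within 1 file set a group has 2 or 3 libraries, and a minimum fold asks for a larger change, so these settings lower a count by construction. Elsewhere the cause was not tested. Depth was not varied, so what it limits was not tested either. Values below are in the order K700E against WT, DDX42 group against K700E, DDX46 group against K700E, DDX42 group against WT, DDX46 group against WT, and DDX42 group against DDX46 group, where the main counts were 0, 382, 1562, 35, 379 and 60.

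With DESeq2 the counts were 2, 855, 2347, 112, 1138 and 204, and with 3 surrogate variables 4, 1576, 2990, 1204, 2958 and 869, where no other splits of the samples were run. With voom and sample weights they were 1, 1543, 235, 733 and 118, leaving out the DDX46 group against K700E, which stayed within 1.5 times. With a replicate block and the file set they were 2348, 3665, 964, 2491 and 215 from the second comparison on. The replicate block without the file set moved 1 count by over 1.5 times, to 701 in the DDX42 group against K700E. In a fit of only the DDX42 and DDX46 groups with a replicate block it was 306. Own numbers correlated best in 13 of 30 pairs. From the second comparison on, file set 1 alone gave 3, 1, 3, 2 and 3, file set 2 alone 3, 1, 2, 1 and 2, a minimum fold of 1.2 gave 18, 42, 9, 12 and 9, and the matrix as deposited 2, 2, 2, 1 and 2. After the GC and length correction the DDX42 group against K700E had 143 (104 of the 382 kept), the DDX46 group against WT 1136 and the DDX42 group against the DDX46 group 111. Fits of only the 2 groups gave 813, 9, 11 and 11 from the third comparison on, and without the file-set covariate the last comparison had 28.

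The SF3B1 difference of the DDX42 group from K700E passed with 3 surrogate variables (log2 fold change 0.32, adjusted p = 0.0298, where the alternatives ran from 0.0298 to 1.00), and that of the DDX46 group fell short within file set 1 (1.21, adjusted p = 0.0751) and set 2 (1.32, adjusted p = 0.0924), where the alternatives ran from 2.02e-16 to 0.0924. The covariance less the shared part, -0.00368 for DDX42 and -0.00285 for DDX46, was -0.0271 for both with DESeq2, -0.0402 and -0.0467 in file set 2, and -0.0462 and -0.0461 over called genes alone. For DDX42 it was also -0.0135 with a replicate block and the file set, -0.0107 without a low-count filter and -0.00982 with voom. The overlap of 255 calls was 571 with DESeq2, 866 with voom, 1058 with surrogate variables, 459 with a replicate block, 1727 with that and the file set, 104 after the GC and length correction, 0 in either file set alone, and 9.1 on average with split K700E libraries.

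Of the lists, main counts 2, 5, 9, 8, 11 and 10, an estimated correlation left 0 in each comparison. By fry 0, 1, 7, 0, 8 and 0 passed. With surrogate variables 5, 8 and 14 passed in the first 3 comparisons. In K700E against WT 7 passed in file set 1 and 5 after the GC and length correction.

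Without 1 library the counts of genes ran from 0 to 0, 56 to 542, 454 to 1951, 13 to 42, 76 to 899 and 16 to 94, and those of lists from 3 to 7, 4 to 7, 9 to 11, 5 to 9, 9 to 12 and 9 to 11. The covariance less the shared part ran from -0.0157 to 0.00714 for DDX42 and from -0.0147 to 0.00879 for DDX46, and the overlap from 27 to 360. SF3B1 log2 fold changes ran from -0.41 to -0.29 in K700E against WT, 0.21 to 0.38 in the DDX42 group against K700E and 1.22 to 1.34 in the DDX46 group against K700E. Those of DDX42 ran from 7.08 to 7.54 against K700E and 7.38 to 7.61 against the DDX46 group, and those of DDX46 from 5.99 to 6.20 against K700E and -5.84 to -5.62 in the DDX42 group against the DDX46 group.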

Other observations

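Chosen only after the results were seen were the tests of the 3 K700E groups together against WT, of surrogate variables, of the GC correction on counts and lists, of the split covariance as an explanation, of the order and construct levels in the sets of libraries, of splits that keep those sets as in the real groups, and of the overlap covariance in other splits. The splits drawn without regard to the sets, the scaling without transfected genes and the GC correction of the first component were set beforehand.

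Setting the 15 libraries with K700E together against the 5 WT libraries, 9 genes passed, 7 besides DDX42 and DDX46, with 914 genes at an unadjusted p under 0.05. PHGDH was lower (log2 fold change -0.25, SE 0.04, adjusted p = 0.0146), below every WT library in 15 of 15, with means of 531 CPM in WT, 464 in K700E, 451 in the DDX42 group and 436 in the DDX46 group. AC004922.1, the uncertain model over ARPC1A and ARPC1B, was lower (log2 fold change -2.36, adjusted p = 0.00771), also in 15 of 15. CCR6 (1.1, adjusted p = 0.00393, above every WT library in 14 of 15), MYLK2 (0.93, adjusted p = 0.0117) and C1orf116 (0.93, adjusted p = 0.0294) were higher, and INKA2 (-0.45, adjusted p = 0.0339) and KANK3 (-0.61, adjusted p = 0.0387) were lower. For the last 4 the means in K700E alone and in WT were 2.66 and 2.39 CPM for MYLK2, 2.17 and 2.11 CPM for C1orf116, 27.0 and 26.5 CPM for INKA2, and 20.4 and 20.1 CPM for KANK3. Above the range of WT lay 12 of 15 libraries for MYLK2, with 1 below it, and on the side of the change 10 of 15 for each of the other 3. With 3 surrogate variables 653 genes passed, with no other splits run at that setting. Other splits of these libraries called up to 301 genes, and 2 of 40 splits, the real one included, gave as many as 9, so chance could not be excluded.

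Of the 26 lists tested, 10 passed in no comparison as first analysed, the smallest adjusted p by camera being 0.105. These were genes described as mis-spliced (smallest adjusted p = 0.188), nonsense-mediated decay factors (0.451), transcripts usually degraded by that pathway (0.176), interferon response (0.437), NF-kB targets (0.876), immediate early genes (0.105), cholesterol biosynthesis (0.176), and markers of blood cells (0.291), fibroblasts (0.241) and squamous or simple epithelium (0.348). After the GC and length correction none of the 10 passed. With 3 surrogate variables 1 did, immediate early genes, lower in K700E than in WT (adjusted p = 0.0111), higher in the DDX46 group than in K700E (adjusted p = 0.0335) and lower in the DDX42 group than in the DDX46 group (adjusted p = 0.0276). By fry the genes described as mis-spliced were lower in the DDX46 group than in WT (adjusted p = 0.0187), and with an estimated correlation none of the 10 passed. In the DDX42 group against K700E 1 mis-spliced gene fell, DVL2 (-0.34), and in the DDX46 group DYNLL1 (0.35) and SERBP1 (0.28) rose. ALB (-1.35) and TF (-0.97), both hepatocyte markers, fell in the DDX46 group against K700E, while that list did not pass there (camera adjusted p = 0.332). The list of nuclear RNAs had 0 members among the genes tested.

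More genes passed against K700E than against WT, by 10.9 times for DDX42 and 4.12 times for DDX46. After the GC and length correction the ratios were 5.50 and 2.06, which argues against GC content and length as the whole cause, though it kept 104 of the 382 calls for DDX42. With 3 surrogate variables the larger ratio was 1.31, but the counts against K700E rose as well, to 1576 and 2990, so the ratio does not show whether structure shared by libraries produced the excess. K700E holds 2, 2 and 1 libraries of the 3 sets described below and each other group 1, 2 and 2. With the counts against K700E taken without its replicate 4, which lies in the first of these sets, and those against WT unchanged, the ratios were 1.60 and 1.198. A smaller group alone can lower a count, and without WT replicate 4 the counts against WT were 17 for DDX42 and 138 for DDX46. These ratios therefore do not show whether the sets produced the excess. A K700E change that the helicases turn back stays open. The covariance lay below 0 in 9 of 10 splits for either helicase, but the splits reuse the same libraries. The different share of the sets in K700E can also make it negative without such a change, and the splits cannot separate these.

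Ribosomal protein, G2 and M, and heat shock lists were higher with both helicases than in K700E, 6 calls in all. Their largest adjusted p by camera was 0.00158 after the GC and length correction, which argues against that trend as the whole cause. It was 7.96e-05 with 3 surrogate variables. These were estimated with the groups kept in the model, so they do not test structure that coincides with the groups. Leaving the transfected genes out of scaling moved the median gene by under 0.01 (log2), so the adjusted p of 0.00272 there decides nothing, and counts taken by those genes stay open. None of the 6 passed with an estimated correlation, and other splits of the samples gave as many lists, as given below. A biological difference between the groups is therefore a hypothesis that these tests leave open.

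Libraries of different groups deviated together in 3 sets, with a median correlation of 0.178 within a set and -0.100 between sets. The sets followed a common order of the replicate numbers within group and file set in 8 of 8 cells (6 of 20736 shuffles, exact p = 2.89e-04), so 3 repeated rounds of the work are a candidate explanation. In 1 set of 7 libraries, picked of the 3 because its SF3B1 was lowest, the transfected helicase was lowest of its group in 2 of 2 groups (exact p = 0.02, two-sided, the smallest possible), so the amount of construct may also differ between sets. A correlation of SF3B1 with the first component, pooled over the sets, was tried first and replaced by a rank test after its value was seen; within sets r was -0.259 in a set of 8 (exact p = 0.555, rho -0.0476) and 0.505 in a set of 7 (exact p = 0.251, rho 0.321), with r of 0.154 and 0.0957 without the 2 farthest libraries. The first component held 21.6% of the residual variance before the GC and length correction and 21.8% after it, which argues against GC content and length.

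Other splits of the samples were counted, 40 per result with the real one included. As many genes passed in 1 split, the real one, for the DDX42 group against K700E (382, highest other 0), the DDX46 group against K700E (1562, highest other 290) and the DDX42 group against WT (35, highest other 1). A share of 1 in 40 is the smallest these splits can give, was not adjusted over the comparisons, and ignores the 3 sets. It argues against chance there without excluding it. Chance could not be excluded for the DDX46 group against WT (379 in 2 splits, highest other 1205) or the helicase groups against each other (60 in 2 splits, highest other 125), and for K700E against WT the real count of 0 makes all 40 splits as large whatever the data (highest other 0), which says nothing of chance. The split with 1205 genes put WT replicates 1 and 2 with DDX46 group replicates 1, 3 and 4, leaving all 4 libraries from the set with the lowest SF3B1 on the other side, which points to a structure of the samples. That with 290 genes put K700E replicates 1 to 4 with DDX46 group replicate 3, so that 3 libraries of 1 set stood on one side and 0 on the other. It exchanges only 1 library of each group against the real split, so its calls may also come from the real difference. The splits that keep the libraries of each set as in the real groups numbered 54 against K700E and 36 in the other 3 comparisons. In each of the 5, 1 of them, the real one, gave as many genes. The highest others were 0 for the DDX42 group (real count 382) and 1 for the DDX46 group (1562) against K700E, 1 (35) and 181 (379) for these against WT, and 0 (60) between them. These counts argue against chance among such splits without excluding it, since the splits are few and the sets were found from the same libraries. Of 16 splits that part every pair of the helicase groups, 1, the real one, gave 60 genes and the highest other gave 0, too few splits for a share under 0.05. Of the 40 splits for the overlap, 1, the real one, gave 255 shared calls and the highest other gave 0, but no other split called genes in both comparisons, so this count says nothing of chance. Its covariance beyond the shared libraries was 0.0245, with 0.0224 as the highest other and 1 split, the real one, as large. These splits do not keep the link between helicase libraries of the same number (r from 0.167 to 0.388), which raises the real covariance. They therefore do not exclude chance, and how much of the covariance that link gives stays open. For the lists, with 2, 5, 9, 8, 11 and 10 calls in the order of the comparisons, 35, 17, 19, 7, 7 and 10 splits gave as many, with highest others of 11, 10, 13, 10, 13 and 14, so chance could not be excluded. For the reversals 13 splits each gave a covariance as low, against -0.00368 and -0.00285, with lowest others of -0.0323 for DDX42 and -0.0220 for DDX46, so chance could not be excluded.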
